A study of Chlorocebus aethiops with 30 samples.

How the data were processed

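RNA sequencing was carried out on Vero cells, an epithelial line from African green monkey kidney, in 30 samples that the labels place in 10 groups of 3. An enzyme-free solution at 37 °C was used for the control group. The remaining groups were detached with trypsin at 37 °C, with TrypLE (a recombinant trypsin substitute) at 37 °C, or with TrypLE taken from 4 °C and applied at 25 °C, and each treatment was sampled at 0, 8 and 24 h. Cells at 0 h were collected directly after digestion, whereas cells at 8 and 24 h had been returned to culture and were then collected with the enzyme-free solution. The replicates are numbered in the labels, and nothing there says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

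Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the gene annotation and the differential test are not given in the sources used here. Gene lengths, symbols and gene numbers were taken as the authors' tables give them. Scaffold positions are left out because the build is not named.

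The deposited comparison of trypsin and TrypLE at 0 h holds 1237 genes, all with an unadjusted p below 0.05 in the authors' test. Its 6 library columns hold a signal that the authors made by dividing the read count of each gene by a size factor for each library. Every value was a whole multiple of the smallest step of its column within a tolerance of 0.01 reads, so that 100% of values gave whole reads in each of the 6 libraries. For replicate 1 of the TrypLE group this rests on fewer low values than in the other libraries. Size factors were 1.0229, 0.98 and 0.9443 for trypsin and 1.0261, 1.0911 and 0.987 for TrypLE. The log2 fold change in the deposited table is trypsin over TrypLE as the authors computed it. The p-value and adjusted p in that table are the authors' own, and the adjusted values are those of a Benjamini-Hochberg adjustment over 15194 genes.

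The deposited union table gives 1 mean per group for 340 genes that the authors selected, in 7 of the 10 groups. Its unit is not named in the header. Over the genes shared with the comparison table, its values equal the normalized count per kilobase divided by 15.76 with a coefficient of variation of 0.0143%, which is an FPKM scale, so the authors' values are called FPKM-scale means here. They carry no error and no n. The 3 groups treated with cold TrypLE, 9 samples in all, were not analysed here. The deposited pathway table gives p-values and adjusted p-values of the authors' KEGG enrichment for 274 pathways, with the number of listed genes in each. A hypergeometric test on 560 listed genes with a pathway annotation and 8172 background genes gave the same p-values.

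The planned test was edgeR on counts of all genes. Since only genes under an unadjusted p of 0.05 are listed, the authors' fold changes and adjusted p are the main result, with a threshold of 0.05 on the adjusted p, and fits on the listed genes describe those genes alone. Group values are the mean and SD of the normalized counts of 3 libraries. Refits used edgeR 4.0.16 (quasi-likelihood test with its default expression filter), DESeq2 1.42.0 and limma 3.58.1 in R 4.3.3, on the recovered reads or on log2(normalized count + 1), with the Benjamini-Hochberg adjustment taken over 15194 genes. The edgeR count test on recovered reads called 170 genes. On simulated counts for the 1237 genes of the trypsin and TrypLE comparison, edgeR recovered 16.4% of 67 genes, 76.1% of 67 genes and 92.4% of 66 genes changed by a log2 fold of 0.5, 1 and 1.5, and called 0 of 1037 unchanged genes. DESeq2 called 1 of these unchanged genes. The simulated counts were drawn independently for each gene and without a trend on gene length. They therefore do not test for false calls from such a trend, and the adjustment over 15194 genes made false calls unlikely. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

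Before the data were examined, 32 gene lists, the rule for named genes and most alternatives were fixed. Where at least 5 members of a list were listed, the number higher and lower was compared with that among the other listed genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 6 lists tested. Camera in limma with an estimated correlation or with the replicate block was chosen then as well and run on the listed genes. The replicate block fit used a preset correlation. Camera with a preset correlation and no block had been planned only for a table of all genes. Its use on the listed genes was added after the data were seen. So was fry, which tests a list against no change and not against other genes. Named genes are the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 50 normalized counts and no overlap between the libraries of the groups. To these were added up to 3 members with the smallest adjusted p from each list with at least 3 listed members. In the union table the rule takes the 5 genes with the largest ratio of highest to lowest group mean, where the highest is at least 1, and up to 2 members of each list with the widest range. The 8 pathways with the smallest adjusted p are named. Results were compared with those from median-ratio size factors, other tools, filters and pseudocounts, each library left out in turn, the replicate number as a block, and stricter thresholds. TMM factors over the listed genes, the edgeR refit with the authors' size factors, limma with a pseudocount of 1 and removal of the trend of each library on gene length were added after the data were seen, as was an exchange of the prior degrees of freedom between the edgeR fits with and without that removal.

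Reads recovered over the listed genes ranged from 1656319 to 2192333 per library. These are parts of the libraries, not their depth, and the total depth is unknown. Pairs of libraries within a group differed by more than sampling noise (chi-square per gene of 8.84 to 58.68, against 54.43 to 179.82 between groups), so no library was counted as a copy of another. Trypsin replicate 1 stood apart, at 58.68 and 39.74 from the other trypsin libraries and 88.75, 55.74 and 54.43 from the TrypLE libraries. The other trypsin libraries lay 10.51 apart. TrypLE replicate 1 stood apart within its group too, at 32.27 and 31.72 from the other TrypLE libraries, which lay 8.84 apart. Genes of large families with processed copies, ribosomal protein genes above all, are uncertain, because counting can split their reads between copies.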

Results

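The data describe RNA levels in Vero cells after detachment by different reagents. Values for single libraries were analysed for 2 groups at 0 h, trypsin and TrypLE at 37 °C, with 3 libraries each. Group means were analysed for these and for 5 further groups, namely the enzyme-free control and both enzymes at 8 and 24 h. Reads over the 1237 genes of the comparison table numbered 1827824, 1659930 and 1656319 in the trypsin libraries and 2192333, 2160269 and 1957344 in the TrypLE libraries. The depth over all genes is not given and was only inferred from the FPKM scale.

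The first comparison asks how cells collected directly after trypsin differ from cells collected directly after TrypLE. Of the immediate early genes, which respond within minutes to outside signals, 13 of 21 listed members passed in the authors' deposited table, as did 34 of 52 ribosomal protein genes and 7 of 14 respiratory chain genes, and all were lower after trypsin. With an estimated correlation these groups did not pass in camera (adjusted p = 0.179, 0.391 and 0.391). After removal of a trend on gene length, ribosomal protein and respiratory chain genes no longer differed in direction from the other listed genes (adjusted p = 0.887 and 0.217 by Fisher's exact test). The trend was fitted on the listed genes, these included, so its removal also takes out a change shared by short genes. HES1, a transcriptional repressor downstream of Notch signalling, had 699 ± 90.6 normalized counts after trypsin and 2241 ± 204 after TrypLE (SD, n = 3 each). DUSP1, a phosphatase that switches off MAP kinases, had 7358 ± 538 and 18299 ± 976. In the authors' deposited table these are log2 fold changes of -1.68 and -1.31, both with an adjusted p of 9.31e-34.

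Of the 1237 listed genes, 251 passed an adjusted p of 0.05 in the authors' deposited table, 35 higher and 216 lower after trypsin, so that 86.1% were lower. Of these, 80 differed by at least 2-fold, 6 higher and 74 lower. An edgeR refit of the listed genes called 170, and 95 without TrypLE replicate 1 and 112 without TrypLE replicate 2. The split between higher and lower moved with the libraries used and with factors taken over the listed genes. With the authors' size factors edgeR called 16 higher and 154 lower (90.6% lower). Higher calls ran from 6 without TrypLE replicate 2 to 33 without trypsin replicate 1. With TMM factors over the listed genes, edgeR called 43 higher and 80 lower (65% lower), and with median-ratio factors 56 higher and 78 lower (58.2% lower). These factors move the median log2 fold change of the genes tested from -0.29 to -0.10. The listed genes were selected for a difference and most were lower, so such factors draw the median towards 0 by construction. Calls lost or gained under them do not show which scaling is right.

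Of the 39 genes on the immediate early list, 18 were not listed, and all 21 listed genes were lower after trypsin. Of these, 13 passed the threshold in the authors' deposited table, and 19 passed when adjusted over the list alone. The Fisher's exact test against the other listed genes gave an adjusted p of 4.01e-05, while camera gave an adjusted p of 0.179 with an estimated correlation. ATF3, a stress-responsive transcription factor, had 683 ± 11.8 normalized counts after trypsin and 1586 ± 39.0 after TrypLE (SD, n = 3 each). DUSP5, a nuclear phosphatase of ERK, had 612 ± 79.5 and 1694 ± 193. NR4A1, an orphan nuclear receptor, had 95.1 ± 20.4 and 301 ± 41.1. In the authors' deposited table their log2 fold changes were -1.22, -1.47 and -1.66, with adjusted p of 6.12e-24, 4.86e-23 and 3.93e-12. Under TMM and median-ratio factors edgeR called 7 of the 21, against 10 with the authors' size factors.

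**Figure D1:**
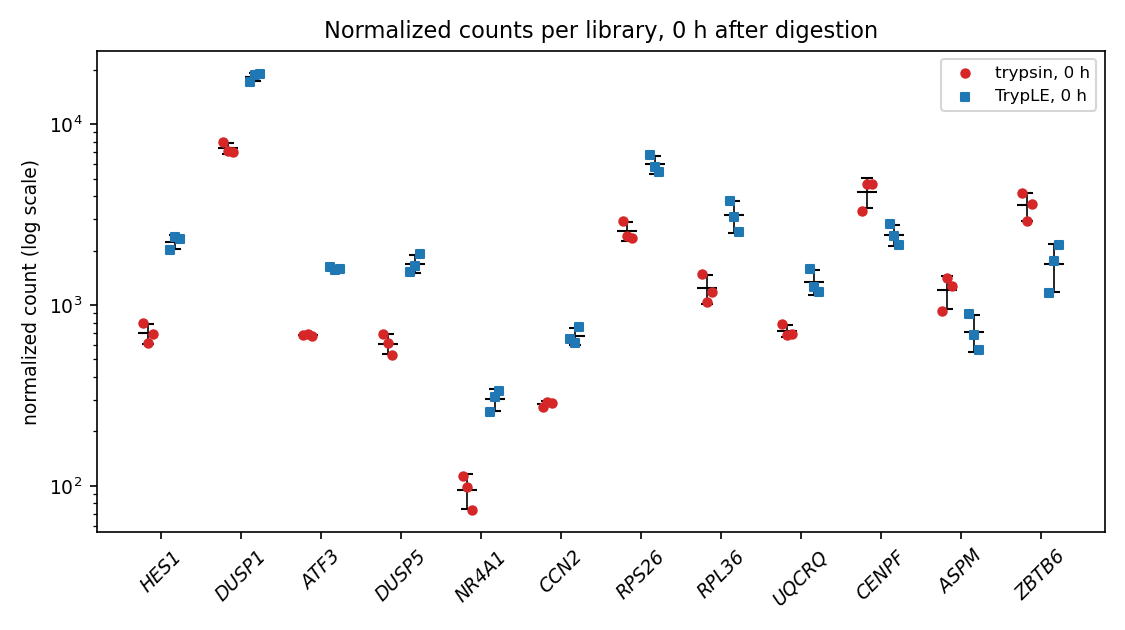
Normalized counts (log scale) of 12 named genes in the 3 trypsin libraries (circles) and the 3 TrypLE libraries (squares) at 0 h, with the mean and SD as black bars. For HES1 the trypsin libraries lie between 613.3 and 793.8 and the TrypLE libraries between 2008.6 and 2391.1.

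Of the 30 symbols on the list of YAP and serum response factor targets, 24 were not listed. The 6 listed members followed the same side, all lower, and 2 passed the threshold, or 3 when adjusted over the list alone. The Fisher's exact test gave an adjusted p of 0.0485, which became 0.0508, 0.051 and 0.051 without trypsin replicate 1, 2 or 3 and 0.0853 among genes with a mean of at least 100. Camera gave an adjusted p of 0.179 with an estimated correlation and 0.0431 with a preset one. CCN2, a matricellular protein, had 284 ± 9.38 normalized counts after trypsin and 674 ± 71.5 after TrypLE (SD, n = 3 each), a log2 fold change of -1.24 with an adjusted p of 1.38e-14 in the authors' deposited table. CCN1, of the same family, had a log2 fold change of -0.53 (adjusted p = 5.8e-06) in the authors' deposited table. In edgeR it was -0.34 under TMM factors (adjusted p = 0.173) and -0.33 under median-ratio factors (adjusted p = 0.144), and its call was also lost in 4 of the 6 refits that leave out 1 library. TAGLN had a log2 fold change of -0.41 that did not pass in the authors' deposited table (adjusted p = 0.0993). The inflammatory list holds 26 genes, of which 17 were not listed. Of its 9 listed members, 8 were lower, 4 passed and 6 passed when adjusted over the list alone. The Fisher's exact test of its direction did not pass (adjusted p = 0.0867), but passed once the length trend was removed (adjusted p = 0.0262). Camera gave an adjusted p of 0.179 with an estimated correlation. IL1A, TNFAIP3 and IL11 had log2 fold changes of -0.62, -0.53 and -0.38 in the authors' deposited table, with adjusted p of 0.0031, 0.00374 and 0.0193. The edgeR refit called 1 member of this list, IL1A, which lost its call under TMM and median-ratio factors (adjusted p = 0.218 and 0.248) and in 5 of the 6 refits that leave out 1 library. IL11 was not called there. TNFAIP3 was not called by edgeR (adjusted p = 0.0831) but was called by DESeq2 (adjusted p = 0.0199), and by edgeR at a log2 fold change of -0.81 with the length trend removed (adjusted p = 0.00195). Of the 27 genes on the p53 and apoptosis list, 23 were not listed. The 4 listed members were lower, and 2 passed, also when adjusted over the list alone. GADD45A and MCL1 had log2 fold changes of -0.66 (adjusted p = 0.000132) and -0.38 (adjusted p = 0.0178) in the authors' deposited table, against -0.34 for BAX (adjusted p = 0.223), which did not pass. MCL1 was called neither by edgeR (adjusted p = 0.299) nor by DESeq2 (adjusted p = 0.0886), but passed in edgeR at a log2 fold change of -0.50 with the length trend removed (adjusted p = 0.012). GADD45A lost its edgeR call under TMM and median-ratio factors (adjusted p = 0.133 each) and in 5 of the 6 refits that leave out 1 library.

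All 52 listed ribosomal protein genes were lower after trypsin and 34 passed the threshold in the authors' deposited table. The Fisher's exact test gave an adjusted p of 7.01e-13, and camera an adjusted p of 0.391 with an estimated correlation. RPS26 had 2558 ± 307 normalized counts after trypsin and 5999 ± 664 after TrypLE, and RPL36 had 1238 ± 227 and 3127 ± 621 (SD, n = 3 each). RPS27 had 1041 ± 101 and 3388 ± 1955, and its TrypLE libraries held 5640.8, 2373.7 and 2148.0. RPL37, RPL38 and RPS29 had log2 fold changes of -1.49, -1.50 and -1.67 in the authors' deposited table. Of the 47 symbols on the oxidative phosphorylation list, 33 were not listed. The 14 listed genes were lower, 7 passed and 10 passed when adjusted over the list alone. The Fisher's exact test gave an adjusted p of 0.000749, and camera an adjusted p of 0.391 with an estimated correlation. COX7A2, a subunit of cytochrome c oxidase, had 1022 ± 49.7 and 1980 ± 342 normalized counts (SD, n = 3 each), and UQCRQ, of complex III, had 718 ± 54.6 and 1341 ± 212. NDUFA4 had a log2 fold change of -0.62 in the authors' deposited table, and UQCRH, a respiratory chain gene outside the fixed list, one of -1.84. Under TMM and median-ratio factors edgeR called 19 and 17 ribosomal protein genes, against 24 with the authors' size factors, and 2 oxidative phosphorylation genes under each, against 6. The medians went from -0.53 to -0.35 and -0.34 for ribosomal protein and from -0.45 to -0.26 and -0.25 for oxidative phosphorylation, and NDUFA4 lost its edgeR call (adjusted p = 0.0991 and 0.105), as it did in 4 of the 6 refits that leave out 1 library.

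These short genes moved with gene length. In the authors' deposited table the genes called lower had a median length of 693 bases and those called higher 5994 bases, and 145 of the 149 called genes under 1000 bases were lower. When the trend on length was removed from each library, edgeR called 63 genes, 22 higher and 41 lower, against 170 before. The prior degrees of freedom that edgeR estimated fell from 20.4 to 6.6 between these fits. When they were exchanged, the fit with the trend removed called 177 genes and the fit without removal 70, so the smaller count does not measure how many changes follow length. The trend was fitted on listed genes that include the ribosomal protein and oxidative phosphorylation genes. Its removal therefore also takes out a change that short genes share, and cannot tell such a change from an effect of length. With the trend removed, ribosomal protein members split into 26 lower and 26 higher and oxidative phosphorylation members into 4 lower and 10 higher. Their direction then no longer differed from that of the other listed genes by Fisher's exact test, with an adjusted p of 0.887 for ribosomal protein and 0.217 for oxidative phosphorylation. Of the ribosomal protein genes edgeR then called 7 lower and 1 higher, and 12 lower and 4 higher with the prior degrees of freedom of the other fit. Of the oxidative phosphorylation genes it called 0, and 1, ATP5MC3, as higher with those degrees of freedom. RPS26 kept its call at a log2 fold change of -0.64 (adjusted p = 0.00265 by edgeR), as did RPL36 and RPL37. COX7A2, UQCRQ and NDUFA4 went to -0.30, -0.17 and -0.21 and lost their calls by edgeR, also with the prior degrees of freedom of the other fit (adjusted p = 0.186, 1 and 0.547). RPL38, RPS27, RPS29 and UQCRH lost theirs only with the smaller prior degrees of freedom. Of the immediate early genes, 20 of 21 remained lower, and 9 were called, or 14 with the prior degrees of freedom of the other fit, against 10 before removal, or 7 with the smaller ones. Trypsin replicate 1 stood apart along length: listed genes under 1000 bases had a median log2 value of -0.11 in it relative to the mean of the 6 libraries, against -0.48 and -0.35 in trypsin replicates 2 and 3 and 0.45, 0.29 and 0.22 in the TrypLE libraries. Without it edgeR called 37 ribosomal protein genes, against 24 with all 6 libraries, and without 1 of the others 17 (TrypLE replicate 1) to 23 (TrypLE replicate 3).

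**Figure D2:**
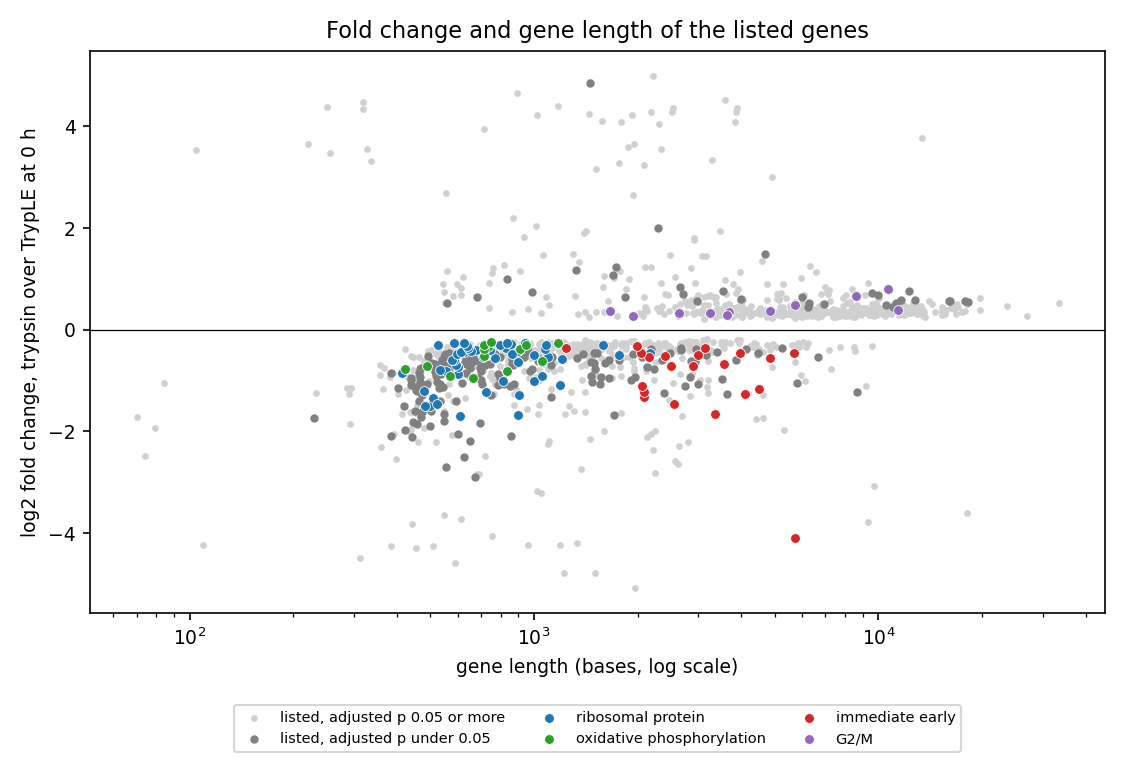
Log2 fold change of trypsin over TrypLE at 0 h in the authors' deposited table against gene length in bases (log scale), 1 point per listed gene, with the members of 4 lists in colour. Listed genes under 500 bases are lower in 91.3% of cases and those of 10000 bases or more in 1.0%, and the gap around 0 comes from the listing of genes by p.

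Of the 31 genes on the G2/M list, 20 were not listed, and all 11 listed genes were higher after trypsin. Of these, 3 passed in the authors' deposited table, and 10 passed when adjusted over the list alone. The Fisher's exact test gave an adjusted p of 0.000172, and camera an adjusted p of 0.179 with an estimated correlation. CENPF, a kinetochore protein of dividing cells, had 4239 ± 792 normalized counts after trypsin and 2446 ± 320 after TrypLE (SD, n = 3 each), a log2 fold change of 0.79 with an adjusted p of 1.23e-05 in the authors' deposited table. CENPE, a mitotic motor, had 750 ± 129 and 472 ± 91.6, and TOP2A, a topoisomerase, 5758 ± 875 and 4132 ± 689. Their adjusted p in the authors' deposited table were 0.00905 and 0.0433, and the edgeR refit called neither with the authors' size factors, while DESeq2 called CENPE (adjusted p = 0.0297). The edgeR call of CENPF was lost without TrypLE replicate 2 (adjusted p = 0.0545). Under TMM factors edgeR called both (adjusted p = 0.0319 each), and under TMM and median-ratio factors 6 of the 11 each, against 1 with the authors' size factors, with the median going from 0.37 to 0.57. With the length trend removed 10 of 11 members stayed higher (adjusted p = 0.025 by Fisher's exact test). CENPF went in edgeR from a log2 fold change of 0.79 (SE 0.153, adjusted p = 0.00458) to 0.41 (SE 0.084, adjusted p = 0.0909). Fold and SE fell together, and with the prior degrees of freedom of the other fit the adjusted p is 0.00705 after removal and 0.0921 before, so the call follows the degrees of freedom. CENPE went from 0.67 to 0.33 and passed at neither (adjusted p = 1 and 0.481 by edgeR). CCNB1, a mitotic cyclin, passed there with a log2 fold change of 0.65 (adjusted p = 0.00777 by edgeR), against 0.37 and 0.422 before. Of the 31 genes on the S phase list, 27 were not listed. The 4 listed S phase genes were higher and 0 passed at an adjusted p of 0.05, as in the count adjusted over the list alone. All 4 are nevertheless below an unadjusted p of 0.05 in the authors' test. BRCA1, UHRF1 and POLA1 had log2 fold changes of 0.32, 0.29 and 0.31 in the authors' deposited table.

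Among the other genes on the higher side, ZBTB6, a zinc finger protein, had 3556 ± 628 normalized counts after trypsin and 1681 ± 494 after TrypLE (SD, n = 3 each), a log2 fold change of 1.08 with an adjusted p of 0.012 in the authors' deposited table. ASPM and KNL1, which act in the spindle and the kinetochore, had log2 fold changes of 0.76 and 0.73 there. In edgeR each stayed called in 3 of the 6 refits that leave out 1 library, and neither with the replicate block. Both are long (12242 and 9590 bases), and with the length trend removed they went to 0.35 and 0.37 and lost their calls in edgeR (adjusted p = 0.62 and 0.504), also with the prior degrees of freedom of the other fit (adjusted p = 0.175 and 0.213). DEPP1, FOXQ1, IER5L and VCPIP1 had log2 fold changes of 0.74, 0.84, 0.70 and 0.68 in the authors' deposited table, and the edgeR refit did not call FOXQ1 or VCPIP1, nor IER5L under TMM factors (adjusted p = 0.0518). IER5L stayed called in 3 of the 6 refits that leave out 1 library. The edgeR call of DEPP1 was lost without trypsin replicate 1 (adjusted p = 0.0636) and without TrypLE replicate 1 (adjusted p = 0.107). Of the 34 genes on the glycolysis and hypoxia list, 31 were not listed. The 3 listed members were lower and 0 passed, as in the count adjusted over the list alone. SLC2A3, TPI1 and PFKFB3 had log2 fold changes of -0.26, -0.22 and -0.26 in the authors' deposited table, and PFKFB3 passed in edgeR only once the length trend was removed (adjusted p = 0.0492). Lists for mitochondrially encoded genes, virus receptors, interferon-stimulated genes and markers of fibroblasts, distal tubule, immune and endothelial cells and of epithelia in general, 8 lists in all, had 0 listed members.

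The pathway table addresses which processes the listed genes fall into. Oxidative phosphorylation led the authors' deposited table, with 53 of the 560 annotated listed genes against 191 of 8172 background genes and an adjusted p of 4.87e-17. Of these 53 genes, 51 were lower after trypsin and 2 higher. Thermogenesis followed with 62 genes, 57 lower (adjusted p = 1.41e-13), then non-alcoholic fatty liver disease with 42, 41 lower (adjusted p = 5.06e-10). Parkinson disease, Huntington disease and Alzheimer disease held 59 listed genes each, with 55, 51 and 52 lower in the authors' deposited table. Cardiac muscle contraction held 20, all 20 lower, and retrograde endocannabinoid signaling 22, of which 20 were lower (adjusted p = 0.0113). These 8 of 274 pathways passed an adjusted p of 0.05 in the authors' deposited table, and they overlap: 97 genes make up all 8, and 53 of these are the oxidative phosphorylation genes. Their median length was 664 bases. The enrichment was tested on all listed genes, not on those past the adjusted threshold.

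The union table places both enzymes beside the enzyme-free control and follows them over time. It holds authors' means without errors for 340 genes that the authors chose on these samples, so directions in it are not independent evidence, and no test was run. HES1 stood at 437.8 in the control on the FPKM scale, at 25.9 after trypsin and 83.3 after TrypLE at 0 h, at 73.8 and 35.9 at 8 h, and at 253.4 and 378.9 at 24 h. EGR1, an immediate early transcription factor, stood at 59.0 in the control. After trypsin it was at 124.4, 21.0 and 42.0 at 0, 8 and 24 h, and after TrypLE at 160.1, 5.78 and 172.3. IL6, a cytokine, stood at 12.5 in the control, 47.7 after trypsin and 59.7 after TrypLE at 0 h, 26.8 and 32.8 at 8 h, and 8.92 and 12.1 at 24 h.

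**Figure D3:**
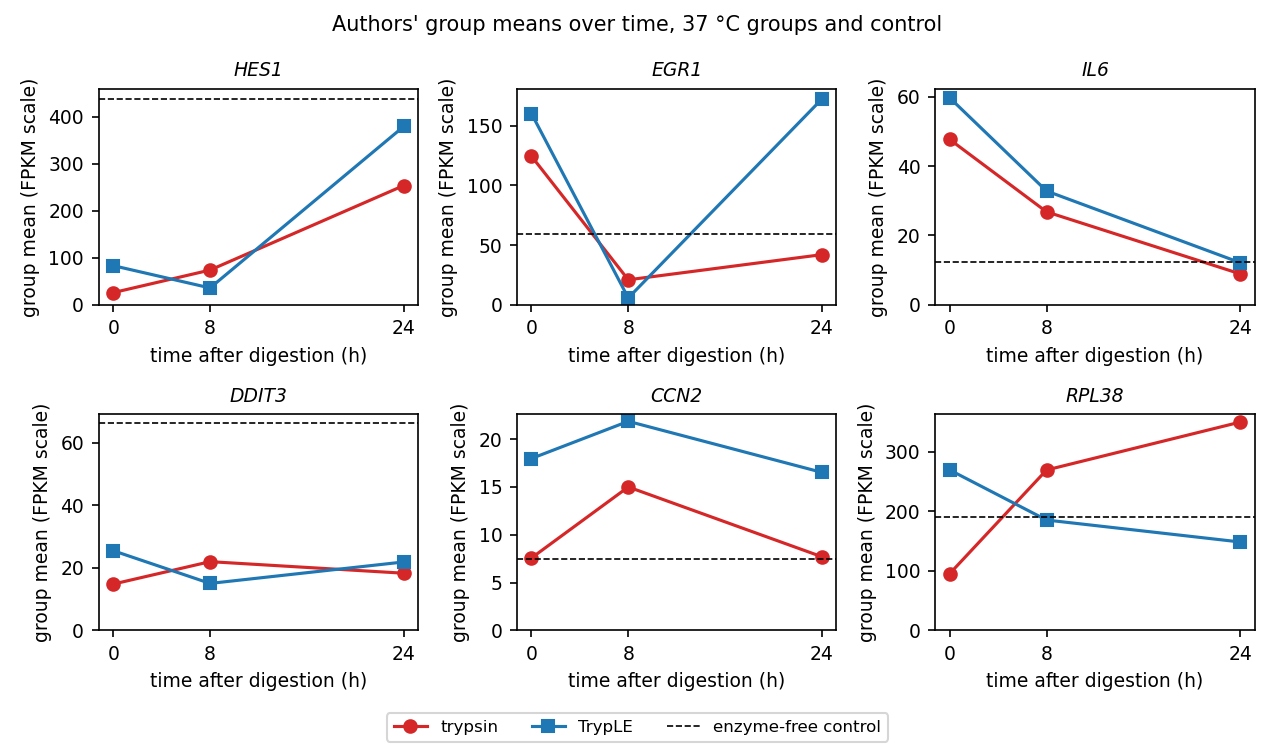
Authors' group means (FPKM scale) of 6 genes at 0, 8 and 24 h after trypsin (circles) or TrypLE (squares) at 37 °C, with the enzyme-free control as a dashed line; no error is given for these means. HES1 lies below the control of 437.8 in all 6 groups, and RPL38 goes from 95.1 to 349.4 after trypsin and from 269.1 to 148.2 after TrypLE.

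By group, the 15 immediate early members in the union table had a median log2(value + 1) difference from the control of -0.48 after trypsin and 0.54 after TrypLE at 0 h. At 8 h the medians were -0.86 and -0.93, and at 24 h -0.69 and 0.11. Set against TrypLE, 15 of these members were lower after trypsin at 0 h, 3 at 8 h and 15 at 24 h. For the 28 ribosomal protein members the medians at 0 h were -0.64 after trypsin and 0.21 after TrypLE, and at 24 h 0.20 and -0.22, so that trypsin lay below TrypLE at 0 h and above it at 24 h. RPS29 went from 26.9 to 111.0 after trypsin and from 86.2 to 48.2 after TrypLE between 0 and 24 h, on the FPKM scale. UQCRQ and NDUFA1 of the respiratory chain stood at 80.0 and 40.7 after trypsin at 0 h and at 129.7 and 68.8 in the control. DDIT3, a transcription factor of the stress response, stood at 66.4 in the control and between 14.8 and 25.5 in the enzyme groups, and DDIT4 at 24.9 and between 9.47 and 16.6. CCN2 stood at 7.48 in the control, at 7.57 after trypsin and 18.0 after TrypLE at 0 h. Between the enzymes, 52 of the 340 genes differed by at least 2-fold on the log2(value + 1) scale at 0 h, 3 higher and 49 lower after trypsin. At 8 h 21 did, 10 higher and 11 lower, and at 24 h 27, 18 higher and 9 lower. Of the 340 genes, 206 are also listed for a difference at 0 h, so these counts cannot show that it fades with time.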

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

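The edgeR refit with the authors' size factors, limma with a pseudocount of 1, TMM factors and removal of the length trend were chosen after seeing the data. So were exchanged prior degrees of freedom, and camera with a preset correlation and fry on the listed genes. Against the authors' 251 called genes, 181 passed an adjusted p of 0.01 and 80 had an absolute log2 fold change of at least 1. The edgeR refit called 170 (162 of them also called by the authors), DESeq2 called 196 (195 shared), TMM factors gave 123, median-ratio factors 134, no low-count filter 160 and the stricter filter 166. Calls by limma were 138 on log2(CPM + 1), 155 with a pseudocount of 1, 141 with 0.1, and 155 with a mean of at least 1. Removal of the length trend gave 63 genes as prior degrees of freedom fell from 20.4 to 6.6; exchanged between the fits, these gave 177 with removal and 70 without. That only listed genes were refitted, with another test, is part of the construction; beyond that the cause was not tested. Leaving out 1 library gave 95 (without TrypLE replicate 1) to 217 (without trypsin replicate 1), and 112 without TrypLE replicate 2, against 170 with all 6.

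Same-numbered libraries had correlations of deviations of 0.024, 0.055 and 0.091, against -0.066 to 0.003 for the other pairs. With 3 libraries per group these small values cannot tell whether same-numbered samples share a batch. With the replicate block edgeR called 167 genes. Of the 32 named genes called by the authors, 16 stayed called in all 6 refits that leave out 1 library and 10 in all 18 refits (HES1, DUSP1, ATF3, DUSP5, NR4A1, CCN2, RPL36, RPL37, RPS26 and ZBTB6). IL11, MCL1 and TNFAIP3 stayed called in 0 of the 6. No named gene reversed in any of the 720 refitted values. Most refits left little room for this: all 1147 genes tested kept the deposited direction in the edgeR refit, and 1145 under TMM factors. With the length trend removed 862 of 1147 did.

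Of the 6 lists tested, 5 passed; with an estimated correlation camera called 0, and 0 at an unadjusted p of 0.05, while camera with a preset correlation called 5. Fry called 6, but it tests a list against no change, not against other genes, and on genes listed for their p a call was close to fixed. After removal of the length trend 4 passed: the ribosomal protein and oxidative phosphorylation lists were lost (adjusted p = 0.887 and 0.217) and the inflammatory list was gained (0.0262). Leaving out 1 library gave 4 to 5 lists, and the call that was lost was that of YAP and serum response factor targets (adjusted p of 0.0508 to 0.051 without a trypsin library), which was also lost with a mean of at least 100 (0.0853). Camera with the replicate block, at the preset correlation, gave this list an adjusted p of 0.06 and the inflammatory list 0.0705. It gave 0.000103 for immediate early, 0.00146 for G2/M, 0.00743 for oxidative phosphorylation and 3.28e-07 for ribosomal protein genes. Their estimated correlations were 0.13, 0.198, 0.706 and 0.757, for which the preset one does not allow. The 8 pathways became 18 at an unadjusted p of 0.05, 16 with lower genes alone and 2 with higher genes alone. The last 2 tests counted only the 260 lower and 162 higher genes found in any pathway. They left out the 138 annotated listed genes in none but kept the background of 8172, so their p-values are too small. In the union table, a pseudocount of 0.1 raised the genes at least 2-fold from the control from 32 to 49 for trypsin at 24 h and from 28 to 44 for TrypLE at 0 h. Leaving out replicates and blocking were not run there, since only group means were analysed. At a log2 fold of 0.5 the simulated recovery with 3 libraries per group was 16.4%; the effect of depth was not tested.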

Other observations

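The match on both gene length and mean count, the separate draws for ribosomal protein and respiratory chain genes, removal of the length trend and the length classes of the union table were chosen after the data were seen; the other draws, the splits and the tests of single libraries were set before their results were seen. Other members of the union table moved on their own courses. NFKBIZ, a regulator of the NF-kappaB response, stood at 28.0 in the control, at 44.4 after trypsin and 56.7 after TrypLE at 0 h, and at 7.63 and 14.2 at 8 h, as authors' means on the FPKM scale. THBS1, a matrix protein, stood at 33.2 in the control and at 11.6 after trypsin and 15.9 after TrypLE at 24 h. PLK1, a mitotic kinase, stood at 61.7 in the control and at 27.8 and 26.3 at 24 h. A gene without a symbol, LOC103219498, stood at 9.45 after trypsin at 0 h, at 5.38 and 3.82 after TrypLE at 8 and 24 h, and between 0.201 and 0.407 in the other 4 groups. Of the stress response list, DDIT3 and DDIT4, chosen after their values were seen, went opposite ways between the enzymes at 0 h, with log2 fold changes of -0.78 (adjusted p = 0.000229) and 0.65 (adjusted p = 0.0152) in the authors' deposited table. Of these 2 the edgeR refit called 1, and 0 with the smaller prior degrees of freedom. With the length trend removed it called 1. With the prior degrees of freedom of the other fit it then called 1 higher and 0 lower. Of the 52 listed ribosomal protein genes, 1 belongs to any pathway of the authors' deposited pathway table, so that table does not show this group.

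The first pattern is that short transcripts were lower and long transcripts higher after trypsin at 0 h. A trend on length that differs between libraries of one group is a candidate explanation: the deviation of single libraries from the others of their group followed length, across genes, with a Spearman's rho above 0.3 in size in 2 of the 6 libraries, trypsin replicates 1 (-0.597) and 2 (0.515), while the largest in TrypLE was 0.115. Deviations within a group of 3 sum to 0, so replicate 1 alone can produce both values, and genes are not independent replicates. By the rule set beforehand, a median at or above that of length-matched draws counts against a fall of ribosomal and respiratory chain genes beyond their length. The observed -0.524 lay above the -0.542 of the draws, a share of 0.667 of 100000 draws being as low (95% lay between -0.686 and -0.455). The drawn genes had a lower mean count, however (median 310.1 against 4665.1), so these draws alone cannot settle it. Matching on mean count as well gave 6e-05 for both groups together and 9e-05 for ribosomal protein genes. That match was still uneven (3225.6 against 4665.1 for both groups together), so for these the question stays open. Respiratory chain genes, at -0.446, lay above the draws on length alone (-0.596, share 0.897). With mean count matched they did so too (-0.457, share 0.551), so no fall beyond length was seen in them. In the union table, 206 genes are also listed in the comparison, and so were selected for a difference at 0 h. Of the 102 under 1000 bases, 101, 49 and 26 lay below the control after trypsin at 0, 8 and 24 h, and 13, 72 and 89 after TrypLE. Of the 24 over 5000 bases, 16 lay below the control after trypsin at 0 h and 20 after TrypLE, so long genes did not rise above the control after trypsin as a group. An effect of the enzyme on these genes was not tested apart from length.

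The second pattern is that immediate early genes were lower after trypsin than after TrypLE at 0 h. The length trend alone is argued against, because a share of 2e-05 of length-matched draws reached the observed median of -0.681, and 1e-05, the smallest these draws can give, when mean count was matched too. These shares may be too small, because the draws take genes as independent. The estimated correlation within this list was 0.13, with which camera gave an unadjusted p of 0.0556. A single library as the source of the calls is argued against as well: of the 10 genes called in the edgeR refit, at least 7 remained called whichever library was left out. No member tested changed direction (21 members, or 20 without TrypLE replicate 1). That part of the rule could not decide, because none of the 1157 to 1164 listed genes tested in these refits changed direction either. A difference in the response of the cells to the 2 enzymes is therefore a hypothesis that these tests leave standing. They also leave standing handling and timing of the digestion, which the labels do not record in a way that could be tested. In the union table, all 15 members were also lower after trypsin than after TrypLE at 24 h (median log2(value + 1) difference -0.74). At 0 h the median was -0.66, and at 8 h it was 0.28, with 12 higher and 3 lower. Cells at 8 and 24 h were collected with the enzyme-free solution. A difference of this size was thus not confined to cells collected directly after digestion. Of the 10 splits of the 6 libraries, 1, the real one, gave as many called genes (170, against at most 5 in the others), on genes that the authors listed for that same split, and 10 splits are too few for a share under 0.05.

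The third pattern is that G2/M genes were higher after trypsin at 0 h. Length-matched draws reached the observed median of 0.371 in a share of 0.163, with drawn genes of lower mean count (430.8 against 2233.6), which leaves the length trend alone as a possible explanation. Against it as the whole cause, the share was 4e-05 when mean count was matched too, and after removal of the length trend 10 of 11 members stayed higher, with a median of 0.323 and an adjusted p of 0.025 by Fisher's exact test. The draws and Fisher's exact test take genes as independent. Camera with the estimated correlation of 0.198 gave an adjusted p of 0.179 before removal. The tests disagree, so the question stays open.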
